A study of Homo sapiens with 72 samples.

How the data were processed

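Total RNA of human subcutaneous and visceral adipose tissue was sequenced as whole tissue, as adipocytes and as the stromal vascular fraction. Per the labels' protocols, collagenase digestion parted floating adipocytes from pelleted stromal vascular cells, the latter were cryopreserved, and stranded total-RNA libraries were made from TRIzol and column-purified RNA. The submitters' processing notes name Trimmomatic 0.35, STAR 2.5.3a, HTSeq 0.6.0 and the genome build GRCh38. The gene annotation, the counting mode and the tool that computed RPKM are not given in the sources used here. The authors deposited RPKM values (reads scaled by gene length and library depth) for 58051 genes in 2 tables, one of whole tissue with 20 columns and one of cell fractions with 44. The 72 samples correspond to 64 columns. Of these 60 stand for 1 library, 2 for 2 libraries and 2 for 4 libraries of the same donor and group. The plan was to average such libraries, but the deposited tables hold them as 1 column, whose making is not given in the sources used here. Each column was used, as 1 sample.

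The tables were normalised separately, so every test was made within 1 table. RPKM depends on the total of each library, so a few abundant RNAs lower all other values of a library. A total-RNA library without poly(A) selection also holds mitochondrial ribosomal RNA, and its share differed between sequencing runs. Low RPKM values were multiples of 1 step per column when multiplied by the exon length in GENCODE 29. From these steps the depth was recovered, and between 94.8% and 98.2% of the values of a column came out as whole reads within a tolerance of 0.1 reads. Gene names and positions were taken from GENCODE 29 on GRCh38, in which 57447 of the 58051 genes were found. Reads of genes with near-identical copies can be assigned to either copy, so the values of C4A and C4B, HBA1 and HBA2, HSPA1A and HSPA1B, the AKR1C genes, the tryptase genes and SAA1 are uncertain. Whether overlapping genes were told apart is also uncertain, since the counting mode is not given. Y-linked genes, XIST and TSIX (517 genes) were left out of all tests because the samples are of persons.

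Groups were taken from the labels. The 6 comparisons were visceral minus subcutaneous in whole tissue (10 and 10 donors), in the stromal vascular fraction (11 and 11) and in adipocytes (10 and 12), adipocytes minus stromal vascular fraction in each depot, and the difference of the depot differences between fractions. Each was tested with limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean-variance trend and robust moderation on log2(RPKM + 0.5), testing both directions, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. A gene was tested where its RPKM was at least 0.5 in at least as many donors as the smaller group had. The sequencing run, read from the titles, was a covariate of 4 levels for the cell fractions. The titles give 5 runs, and 2 adipocyte columns that combine libraries of 2 runs were coded as the earlier one. In whole tissue all subcutaneous libraries were in 1 run and all visceral ones in another, so no run term could be fitted. The last 3 comparisons came from 1 fit of the 4 groups of cell fractions. Shared calls were tested with Fisher's exact test. The design, the gene lists, the rule for named genes and most alternatives were set before the data were examined.

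Donor codes in the labels pair the samples, and the fits reported first have no donor term. The correlation of the deviations of the samples of 1 donor from their group means averaged 0.26 in whole tissue (over 0.1 in 10 of 10 donors), 0.19 in the stromal vascular fraction (8 of 11), 0.21 in adipocytes (7 of 8, a donor alone in a run left out) and 0.13 between fractions in either depot (7 of 10 and 5 of 8). Values with the donor as a block are given where they change a call or a count by more than 1.5 times. No sample was a duplicate of another of its group: the lowest chi-square per degree of freedom between recovered reads of a pair was 10.3.

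The 26 gene lists were of mesothelial cells, HOX genes, other positional transcription factors, mature adipocytes, lipogenesis, lipolysis, adipokines, extracellular matrix, preadipocytes and stromal progenitors, macrophages and monocytes, T and NK cells, B and plasma cells, mast cells, blood endothelium, lymphatic endothelium, smooth muscle and pericytes, red blood cells, inflammatory cytokines and chemokines, immediate early and heat shock genes (tissue handling), complement, thermogenic adipocytes, oxidative phosphorylation, glucocorticoid response, sex steroid receptors and metabolism, Wnt ligands and antagonists, and cell cycle. Some genes are in more than 1 list. Each list was tested with camera in limma with a preset correlation of 0.01, adjusted over the lists of the comparison, and again with an estimated correlation. Camera compares a list with all other genes, so its sign can differ from that of the list's median.

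Named genes were, per comparison, the 8 with the largest difference in each direction among called genes with a mean of at least 2 RPKM in the higher group and the same sign in at least 80% of donors with both sides (for the difference between fractions 5, without the donor condition), and the 3 called members of largest difference of each list or, where none was called, its most abundant member. Unnamed clones, antisense and small RNA genes, pseudogenes and immune receptor segments were not named. From the top of this order the text names at most 5 per direction, 2 per list that passed and 1 per other list. This depth was chosen after the values were seen, and some genes it gives are not reported here.

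The test was tried on simulated data: reads were drawn for the real genes at the real depths with 200 genes changed. For whole tissue (20151 genes) 49 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 61 of 66 changed 4-fold were recovered, with 2.98% false calls. For the stromal vascular fraction (18885 genes) these were 24, 54 and 61, with 5.44%, for adipocytes (14094 genes) 28, 52 and 61, with 4.08%, and for the subcutaneous fractions (20771 genes) 23, 43 and 61, with 3.05%.

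Alternatives were a pseudocount of 0.1 or 1, no filter or a mean RPKM of at least 1, rescaling of each sample by the median of its ratios to the geometric mean, no trend, the donor as a fixed block or random effect, no run covariate, single runs, donors with both depots only, and a minimum difference of 1 log2 unit. Others were chosen after seeing the data: leaving out the 2 shallowest visceral adipocyte libraries, the stromal vascular library rich in hemoglobin or the one with the most genes detected, scaling to reads outside mitochondrial, hemoglobin and 7S RNA genes, limma voom on recovered reads, and, in whole tissue, a correction of each library for a smooth trend (4 degrees of freedom) in GC content and gene length. Other splits of the samples were drawn 100 times per comparison, the real one included, and the random gene lists 1000 times. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.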

Results

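The series compares RNA of subcutaneous and visceral adipose tissue of obese individuals, and its labels give 6 groups. Whole tissue came from 10 donors with both depots. The stromal vascular fraction, the cells other than adipocytes that remain after digestion, came from 11 subcutaneous and 11 visceral samples of 11 donors. Adipocytes came from 12 subcutaneous and 10 visceral samples, with 9 donors in both depots. Libraries of whole tissue held between 10.0 and 30.2 M reads in genes. In the cell fractions 25 libraries of the latest sequencing run held 0.638 to 13.4 M, and 19 libraries of earlier runs held 19.2 to 101 M. Across all libraries 1 read in a gene of 1 kb stood for 0.00987 to 1.57 RPKM, the highest of these in a visceral adipocyte library. Mitochondrial ribosomal RNA made up 3.24% to 41.3% of the reads in the latest run and 0.0543% to 0.773% in earlier runs of the cell fractions. Hemoglobin genes took a median of 1.82% of the reads in the subcutaneous stromal vascular fraction, and 42.4% in its highest library. Both shares lower the RPKM of all other genes in the same library.

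**Figure D1:**
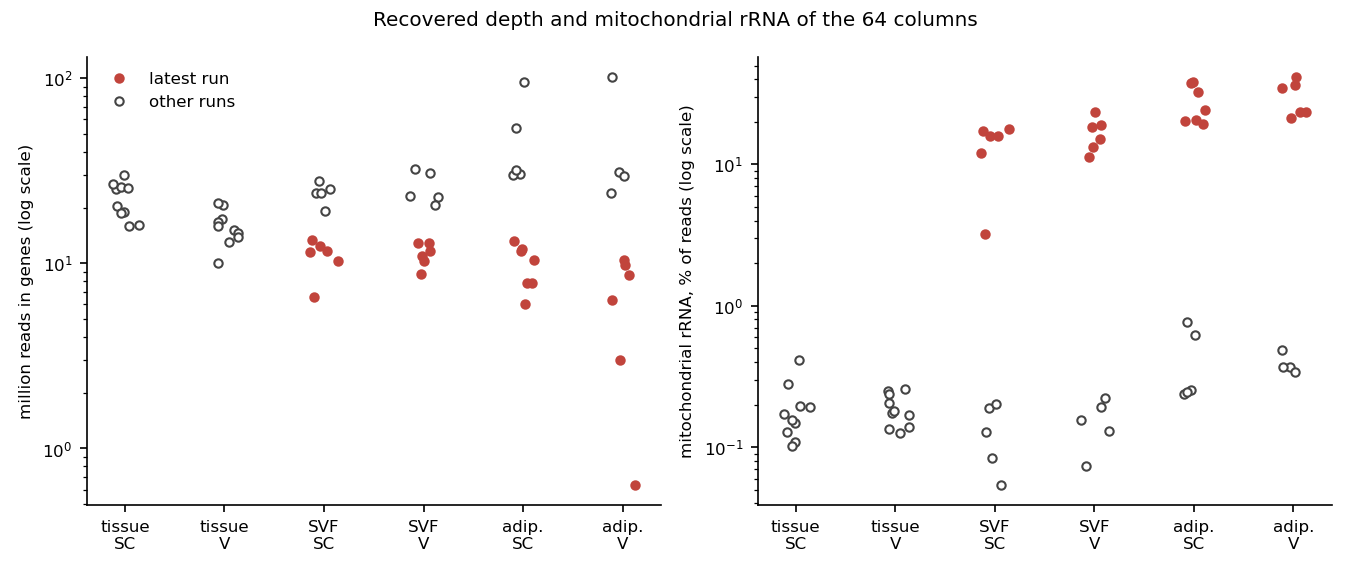
Reads in genes (M, left) and the percent of reads in mitochondrial ribosomal RNA (right), both on log axes, by group for the 64 libraries or combined libraries. Filled points are the latest run, which had fewer reads and more mitochondrial ribosomal RNA than earlier runs of the cell fractions.

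Visceral and subcutaneous whole tissue differed in genes of the mesothelium, the cell layer that covers visceral fat, and, in both directions, in genes of positional identity. ITLN1 (ENSG00000179914, chromosome 1, 160876539 to 160885170 on GRCh38), which encodes the secreted lectin omentin, rose from 9.11 ± 9.55 to 598 ± 479 RPKM (SD, n = 10 each), a log2 difference of 6.27 ± 0.71 (SE, adjusted p = 3.29e-06). MSLN (ENSG00000102854, chromosome 16, 760762 to 768865), the mesothelial surface protein mesothelin, rose from 0.438 ± 0.559 to 23.7 ± 11 RPKM, a difference of 4.68 ± 0.32, adjusted p = 2.28e-09. TBX15 (ENSG00000092607, chromosome 1, 118883046 to 118989556), a transcription factor gene of the embryonic trunk and limbs, was lower in visceral tissue, at 1.01 ± 0.317 against 12.6 ± 2.46 RPKM, a difference of -3.12 ± 0.12, adjusted p = 2.28e-13. EGFL6 (ENSG00000198759, chromosome X, 13569605 to 13633575), which encodes a secreted matrix protein with EGF repeats, was also lower, at 3.85 ± 2.83 against 109 ± 76.3 RPKM, a difference of -4.48 ± 0.52, adjusted p = 5.13e-06. Differences here and below are log2 values ± SE, and each gene called in whole tissue and named here had the same sign in at least 8 of 10 donors.

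Among genes with large differences outside these, LINC02360, a long noncoding RNA gene, and ALOX15, which encodes an arachidonate lipoxygenase, were higher in visceral tissue (4.80 ± 0.48, adjusted p = 7.65e-07 and 4.67 ± 0.36, adjusted p = 1.71e-08). LINC01239, another noncoding RNA gene, and XG, the gene of a blood group antigen, were lower (-2.76 ± 0.27, adjusted p = 5.1e-07 and -2.68 ± 0.16, adjusted p = 2.93e-10). Of 19 mesothelial genes tested, 18 were higher and 0 lower (18 and 0 adjusted over the list alone, camera adjusted p = 2.43e-27, or 0.0463 with an estimated correlation). They included PKHD1L1 (ENSG00000205038, chromosome 8, 109362477 to 109530330), with a difference of 4.94 ± 0.42, adjusted p = 6.47e-08. Of 24 HOX genes, which set position along the body axis, 9 were higher and 8 lower (9 and 9 adjusted over the list alone, camera adjusted p = 0.00198, or 0.47 with an estimated correlation). HOXC8 (ENSG00000037965, chromosome 12, 54009106 to 54012362) and HOXC9 were lower in visceral tissue, by differences of -2.69 ± 0.11, adjusted p = 3.61e-13, and -2.57 ± 0.08, adjusted p = 3.17e-14. Of 24 other positional transcription factor genes, 10 were higher and 13 lower (10 and 13 adjusted over the list alone, camera adjusted p = 0.00595, or 0.421 with an estimated correlation). WT1 (ENSG00000184937, chromosome 11, 32387775 to 32435630), a factor of the mesothelium and kidney, and NR2F1 (ENSG00000175745, chromosome 5, 93583224 to 93594615), a nuclear receptor, were higher (4.09 ± 0.26, adjusted p = 1.23e-09 and 3.14 ± 0.13, adjusted p = 5.26e-13).

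Camera placed the lymphatic, complement and Wnt lists above the other genes in visceral tissue. Of 7 lymphatic endothelial genes, 7 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 2.2e-07, or 0.0463 with an estimated correlation). CCL21, a chemokine made by lymphatic vessels, differed by 3.05 ± 0.34, adjusted p = 3.21e-06, and MMRN1, a multimerin, by 2.53 ± 0.36, adjusted p = 4.49e-05. Of 15 complement genes, 6 were higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.00595, or 0.47 with an estimated correlation). C7, a part of the membrane attack complex, differed by 3.20 ± 0.27, adjusted p = 7.09e-08, and C4B, whose reads cannot be told from those of C4A, by 2.20 ± 0.34, adjusted p = 0.000138. Of 12 genes of Wnt ligands and antagonists, 7 were higher and 1 lower (7 and 1 adjusted over the list alone, camera adjusted p = 0.00304, or 0.196 with an estimated correlation). RSPO1, which amplifies Wnt signals, differed by 3.32 ± 0.36, adjusted p = 1.86e-06, and the ligand gene WNT5A by 2.04 ± 0.14, adjusted p = 2.41e-09.

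Camera placed the lists that follow below the other genes. Of 20 mature adipocyte genes, 0 were higher and 3 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.00354, or 0.695 with an estimated correlation). DGAT2, a triglyceride synthesis enzyme, fell by 1.25 ± 0.41 (adjusted p = 0.0427), a call lost without the filter on low values (adjusted p = 0.0636), and the hormone gene LEP differed by -0.91 ± 0.21, adjusted p = 0.00412. Of 18 lipogenesis genes, 0 were higher and 3 lower (1 and 5 adjusted over the list alone, camera adjusted p = 0.00277, or 0.612 with an estimated correlation). The lipid droplet gene PNPLA3 differed by -0.90 ± 0.19, adjusted p = 0.00218, and the synthesis gene DGAT1 by -0.80 ± 0.16, adjusted p = 0.00133. Of 20 extracellular matrix genes, 2 were higher and 10 lower (3 and 11 adjusted over the list alone, camera adjusted p = 4.04e-05, or 0.169 with an estimated correlation). The protease inhibitor gene TIMP1 was higher (1.48 ± 0.25, adjusted p = 0.000301) and the matrix glycoprotein gene SPARC lower (-1.00 ± 0.18, adjusted p = 0.000505). Of 15 genes of preadipocytes and stromal progenitors, 1 was higher and 3 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.0216, or 0.463 with an estimated correlation). The chemokine gene CXCL14 differed by -1.78 ± 0.35, adjusted p = 0.00141, and MFAP5, of elastic fibers, by -1.59 ± 0.24, adjusted p = 9.42e-05. Of 8 mast cell genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.0262, or 0.612 with an estimated correlation), and the chymase gene CMA1 differed by -1.40 ± 0.33, adjusted p = 0.00614. Of 12 genes of smooth muscle and pericytes, 1 was higher and 4 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.0165, or 0.47 with an estimated correlation). NOTCH3, a receptor of mural cells, and the proteoglycan gene CSPG4 differed by -1.00 ± 0.16, adjusted p = 0.000147, and -0.75 ± 0.19, adjusted p = 0.0117. Of 4 red blood cell genes, 0 were higher and 4 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.000112, or 0.186 with an estimated correlation). The hemoglobin gene HBB differed by -1.77 ± 0.37, adjusted p = 0.00214, and HBA1, whose reads cannot be told from those of HBA2, by -1.59 ± 0.40, adjusted p = 0.00861. Of 12 genes of sex steroid receptors and metabolism, 1 was higher and 4 lower (1 and 7 adjusted over the list alone, camera adjusted p = 7.36e-05, or 0.169 with an estimated correlation). AKR1C1, a steroid reductase gene with near-identical relatives, differed by -1.15 ± 0.19, adjusted p = 0.000249.

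The other 12 lists did not pass in whole tissue, with camera adjusted p between 0.0773 and 0.98. Called genes, higher and lower, with those adjusted over the list alone in parentheses, were 0 and 2 (0 and 2) of 17 for lipolysis, 4 and 2 (4 and 2) of 16 for adipokines, 2 and 0 (1 and 0) of 18 for macrophages and 2 and 0 (2 and 0) of 14 for T and NK cells. They were 0 and 0 (0 and 0) of 3 for B and plasma cells, 1 and 1 (1 and 1) of 12 for blood endothelium, 2 and 0 (2 and 0) of 17 for inflammatory cytokines and 3 and 0 (3 and 0) of 20 for immediate early and heat shock genes. They were 2 and 0 (2 and 0) of 8 for thermogenic genes, 0 and 0 (0 and 0) of 28 for oxidative phosphorylation, 1 and 3 (2 and 3) of 15 for glucocorticoid response and 0 and 0 (0 and 0) of 9 for the cell cycle. The medians of inflammatory, oxidative phosphorylation, glucocorticoid and cell cycle genes were 0.09, 0.05, 0.10 and 0.05, while camera placed these lists below the other genes. Among members of these lists ADRA2A, an adrenergic receptor gene, was lower (-0.71 ± 0.18, adjusted p = 0.00962), and LYVE1, a hyaluronan receptor gene, was higher (0.77 ± 0.22, adjusted p = 0.0222). CCL5, a T cell chemokine gene (1.08 ± 0.25, adjusted p = 0.00557), and KDR, a VEGF receptor gene (0.85 ± 0.15, adjusted p = 0.000667), were higher. So were the cytokine gene LIF (0.97 ± 0.23, adjusted p = 0.00614) and HSPA1B, a heat shock gene with a near-identical copy (1.28 ± 0.28, adjusted p = 0.00305). EBF2, a factor of brown and beige adipocytes, was higher (0.84 ± 0.10, adjusted p = 4.64e-06), and MT1X, a metallothionein gene, was lower (-0.81 ± 0.24, adjusted p = 0.0259). Values of members not called were 0.60 ± 0.66, adjusted p = 0.591 for JCHAIN (positive in 7 of 10 donors), 0.08 ± 0.11, adjusted p = 0.689 for ATP5F1B (4 of 10) and 0.07 ± 0.08, adjusted p = 0.595 for PCNA (6 of 10).

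In all 3209 of 20283 genes tested were called in whole tissue, 2329 higher and 880 lower in visceral fat, and 534 of them differed by at least 1 log2 unit. With the donor as a fixed block 4994 genes were called, and with the donor as a random effect 5399. Depot and sequencing run cannot be told apart within whole tissue, since each depot was sequenced in its own run. The share of calls that were higher was 72.6% as deposited and 47.3% after rescaling by the median of ratios, which also ended the calls of the lists of other positional factors, mature adipocytes, preadipocytes, mast cells and smooth muscle (adjusted p = 0.141, 0.0525, 0.0991, 0.113 and 0.101).

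**Figure D2:**
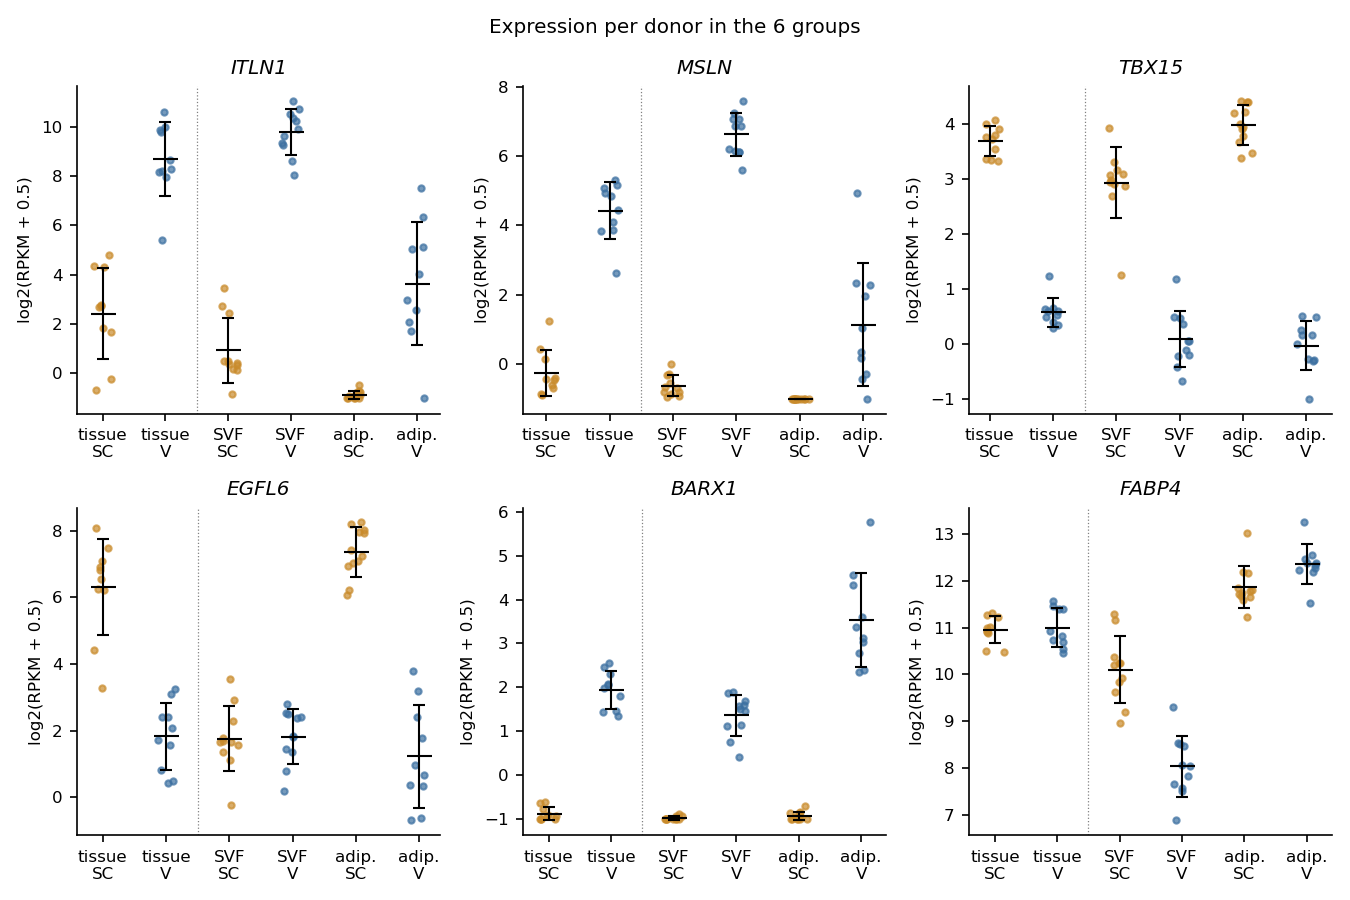
log2(RPKM + 0.5) of ITLN1, MSLN, TBX15, EGFL6, BARX1 and FABP4 per donor in the 6 groups, with bars for the mean ± SD. The dotted line parts the separately normalised tables of whole tissue and cell fractions, whose levels are not comparable.

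In the stromal vascular fraction mesothelial genes also stood out in the visceral depot, and of the lists below only theirs passed with an estimated correlation. ITLN1 rose from 2.44 ± 3.28 to 1042 ± 573 RPKM (SD, n = 11 each), a difference of 8.87 ± 0.47, adjusted p = 1.87e-12. KRT18 (ENSG00000111057, chromosome 12, 52948871 to 52952901) and KRT8 (ENSG00000170421, chromosome 12, 52897187 to 52949954), keratins of simple epithelia, rose from 0.723 ± 0.3 to 199 ± 107 and from 0.239 ± 0.168 to 86 ± 39.2 RPKM, differences of 7.21 ± 0.22, adjusted p = 1.19e-16, and 6.78 ± 0.20, adjusted p = 6.57e-17. FABP4 (ENSG00000170323, chromosome 8, 81478419 to 81483263), the fatty acid binding protein of adipocytes, fell from 1225 ± 637 to 288 ± 141 RPKM (-2.06 ± 0.28, adjusted p = 1.09e-05). Each gene called in this fraction and named here had the same sign in at least 9 of 11 donors.

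MSLN and CLDN1, a tight junction gene, were also among the genes with the largest increases (7.25 ± 0.20, adjusted p = 6.57e-17 and 6.58 ± 0.26, adjusted p = 1.36e-14). Large decreases were in XG (-3.36 ± 0.21, adjusted p = 2.33e-11), the transcription factor gene IRX1 (-2.99 ± 0.19, adjusted p = 5.75e-11) and TBX15 (-2.84 ± 0.24, adjusted p = 4.41e-09). GDF10 (ENSG00000266524, chromosome 10, 47300386 to 47313547), a ligand of the TGF-beta family, differed by -2.95 ± 0.19, adjusted p = 7.55e-11, and CTHRC1, a secreted collagen-related protein, by -2.92 ± 0.20, adjusted p = 1.6e-10. Of 20 mesothelial genes, 19 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 5.67e-55, or 0.0032 with an estimated correlation). Of 15 complement genes, 9 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 1.72e-07, or 0.152 with an estimated correlation). CFB, of the alternative pathway (3.41 ± 0.28, adjusted p = 4.26e-09), and C4B (3.21 ± 0.25, adjusted p = 1.87e-09) were among them. Of 20 inflammatory cytokine and chemokine genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0197, or 0.639 with an estimated correlation). The chemokine gene CXCL6 (2.70 ± 0.26, adjusted p = 4.08e-08) and LIF (1.89 ± 0.21, adjusted p = 4.41e-07) were among them. Of 20 immediate early and heat shock genes, which respond to tissue handling, 6 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.0125, or 0.639 with an estimated correlation). HSPA1B (1.22 ± 0.33, adjusted p = 0.0115) and the orphan receptor gene NR4A1 (1.01 ± 0.21, adjusted p = 0.00144) were among them. Of 13 Wnt genes, 6 were higher and 2 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.0199, or 0.382 with an estimated correlation), and with the donor as a block the adjusted p was 0.0672. RSPO1 and WNT5A were higher (4.91 ± 0.19, adjusted p = 8.33e-15 and 2.49 ± 0.16, adjusted p = 7.24e-11). Of 15 adipokine genes, 4 were higher and 0 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.0416, or 0.496 with an estimated correlation). This list did not pass with the donor as a block (adjusted p = 0.101) or without the library richest in hemoglobin (adjusted p = 0.0591), and GREM1, a BMP antagonist, differed by 2.90 ± 0.28, adjusted p = 4.32e-08.

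Of 20 mature adipocyte genes, 0 were higher and 11 lower (0 and 15 adjusted over the list alone, camera adjusted p = 4.07e-10, or 0.382 with an estimated correlation). CIDEC, a lipid droplet gene, differed by -1.84 ± 0.41, adjusted p = 0.00263. Of 16 lipolysis genes, 1 was higher and 5 lower (2 and 6 adjusted over the list alone, camera adjusted p = 0.0196, or 0.496 with an estimated correlation). The hormone-sensitive lipase gene LIPE (-1.27 ± 0.32, adjusted p = 0.00715) and the lipid droplet gene PLIN1 (ENSG00000166819, chromosome 15, 89664365 to 89679427; -1.25 ± 0.39, adjusted p = 0.0327) were among them. Of 20 matrix genes, 2 were higher and 14 lower (2 and 14 adjusted over the list alone, camera adjusted p = 1.23e-08, or 0.382 with an estimated correlation), with TIMP1 higher (2.49 ± 0.24, adjusted p = 3.83e-08) and the periostin gene POSTN lower (-2.19 ± 0.32, adjusted p = 3.12e-05). Of 12 blood endothelial genes, 0 were higher and 8 lower (0 and 10 adjusted over the list alone, camera adjusted p = 5.87e-06, or 0.382 with an estimated correlation). VWF, the von Willebrand factor (-1.63 ± 0.38, adjusted p = 0.00436), and the cadherin gene CDH5 (-1.53 ± 0.42, adjusted p = 0.0132) were among them. Of 12 smooth muscle and pericyte genes, 1 was higher and 5 lower (1 and 6 adjusted over the list alone, camera adjusted p = 0.00201, or 0.496 with an estimated correlation). DES, a muscle filament gene, was higher (3.04 ± 0.26, adjusted p = 7.31e-09) and NOTCH3 lower (-1.63 ± 0.31, adjusted p = 0.000662). Of 8 mast cell genes, 0 were higher and 2 lower (0 and 3 adjusted over the list alone, camera adjusted p = 0.00201, or 0.382 with an estimated correlation). These were CMA1 (-1.28 ± 0.33, adjusted p = 0.00826) and the tryptase gene TPSAB1 (-0.78 ± 0.24, adjusted p = 0.0278). Of 11 sex steroid genes, 1 was higher and 5 lower (1 and 8 adjusted over the list alone, camera adjusted p = 0.000286, or 0.382 with an estimated correlation). AKR1C2 (-1.60 ± 0.22, adjusted p = 1.13e-05) and AKR1C1 (-1.52 ± 0.21, adjusted p = 1.04e-05), whose reads can be shared, were among them. Of 13 cell cycle genes, 0 were higher and 4 lower (0 and 9 adjusted over the list alone, camera adjusted p = 2.48e-05, or 0.382 with an estimated correlation). The proliferation marker MKI67 (-0.67 ± 0.22, adjusted p = 0.0408) and the nucleotide reductase gene RRM2 (-0.59 ± 0.19, adjusted p = 0.0357) were among them.

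The other 12 lists did not pass, with camera adjusted p between 0.052 and 0.965. These were the lists of HOX genes, other positional factors, lipogenesis, preadipocytes, macrophages, T and NK cells, B and plasma cells, lymphatic endothelium, red blood cells, thermogenic adipocytes, oxidative phosphorylation and glucocorticoid response. The medians of HOX and thermogenic genes were 0.09 and 0.23, while camera placed both below the other genes. The red blood cell list passed with the donor as a block (adjusted p = 0.0474). Without the library richest in hemoglobin other positional factors, preadipocytes, T and NK and B and plasma cells passed (0.0413, 0.0346, 0.0484 and 0.0462), and without the one with most genes detected HOX genes, other positional factors and macrophages (0.0106, 0.00296 and 0.0464). Of their members HOXC9 (-2.18 ± 0.13, adjusted p = 1.01e-11), the lipogenic regulator gene THRSP (-1.77 ± 0.47, adjusted p = 0.0111), CXCL14 (-1.98 ± 0.31, adjusted p = 5.32e-05) and COX7A1, of the respiratory chain (-1.04 ± 0.26, adjusted p = 0.00832), were lower. WT1 (5.23 ± 0.19, adjusted p = 2.29e-15), the macrophage receptor gene MARCO (2.43 ± 0.34, adjusted p = 1.45e-05) and CCL5 (0.96 ± 0.32, adjusted p = 0.0423) were higher. The plasma cell gene JCHAIN (1.58 ± 0.48, adjusted p = 0.0276), the podoplanin gene PDPN (2.88 ± 0.26, adjusted p = 1.92e-08) and H6PD, a hexose phosphate dehydrogenase gene (0.65 ± 0.17, adjusted p = 0.0109), were also higher. Values not called were -0.75 ± 0.52, adjusted p = 0.374 for HBB (negative in 5 of 11 donors) and -0.00 ± 0.08, adjusted p = 0.99 for ATP5F1B (7 of 11).

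In this fraction 2969 of 18993 genes were called, 1846 higher and 1123 lower, and 1080 by at least 1 log2 unit. The share that was higher was 62.2% as deposited, 49.2% after median-of-ratios rescaling and 48.6% of 3862 calls without the library richest in hemoglobin, without which MKI67 was not called (adjusted p = 0.0575). CCL5 was not called after that rescaling (adjusted p = 0.0597) or when scaled to reads outside mitochondrial, hemoglobin and 7S RNA genes (0.0544). Without the filter PLIN1, CCL5, MKI67 and RRM2 were not called (0.0586 to 0.0738), and without the run covariate CCL5, JCHAIN, TPSAB1 and MKI67 were not (0.0531 to 0.0864). Without the library with most genes detected CCL5, MKI67 and RRM2 were not (0.0561 to 0.0675). In the latest run alone 838 genes were called, 705 higher, and 17 genes named above were not called there (adjusted p 0.0693 to 0.590). They were CIDEC, THRSP, LIPE, PLIN1, CCL5, JCHAIN, CMA1, TPSAB1, VWF, CDH5, NOTCH3, HSPA1B, NR4A1, COX7A1, H6PD, MKI67 and RRM2. In the earlier run JCHAIN, CMA1, TPSAB1, HSPA1B, H6PD, MKI67 and RRM2 were not called (0.0711 to 0.347).

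In adipocytes the depots differed in single positional and matrix genes, and no list passed with an estimated correlation. BARX1 (ENSG00000131668, chromosome 9, 93951622 to 93955372), a homeobox gene of the stomach wall, rose from 0.0238 ± 0.0339 RPKM in 12 subcutaneous samples to 15 ± 15 in 10 visceral ones (SD), a difference of 4.47 ± 0.29, adjusted p = 6.04e-10. NR2F1 rose from 2.34 ± 1.16 to 13.1 ± 1.96 RPKM, a difference of 2.34 ± 0.17, adjusted p = 5.05e-09. EGFL6 fell from 182 ± 82.9 to 3.42 ± 4.4 RPKM (-6.13 ± 0.48, adjusted p = 1.49e-08), and TBX15 from 15.8 ± 3.88 to 0.518 ± 0.288 (-4.02 ± 0.17, adjusted p = 2.77e-13). Genes called in adipocytes and named here had the same sign in at least 8 of 9 donors with both depots.

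Other large increases were in LINC02458, a noncoding RNA gene (2.53 ± 0.38, adjusted p = 0.000117), HAS1, a hyaluronan synthase gene (2.31 ± 0.64, adjusted p = 0.0258), and C7 (2.26 ± 0.59, adjusted p = 0.0177), whose call was lost without the 2 shallowest visceral libraries (adjusted p = 0.0557). Visceral values of HAS1 and C7 varied (12.6 ± 30.2 and 17.03 ± 20.52 RPKM), as did the mesothelial gene ITLN1 (36.3 ± 56.6, against 0.0488 ± 0.0673), and whether mesothelial cells are their source was not tested. Large decreases were in NRCAM, a cell adhesion gene (-4.05 ± 0.32, adjusted p = 1.23e-08), and MFAP5 (-3.50 ± 0.27, adjusted p = 1.02e-08). Of 17 HOX genes, 5 were higher and 8 lower (6 and 8 adjusted over the list alone, camera adjusted p = 0.00439, or 0.411 with an estimated correlation). This list did not pass with the donor as a block (adjusted p = 0.105), and HOXC8 and HOXC9 differed by -3.25 ± 0.13, adjusted p = 1.45e-13, and -3.08 ± 0.19, adjusted p = 4.32e-10. Of 20 other positional factors, 6 were higher and 11 lower (6 and 11 adjusted over the list alone, camera adjusted p = 0.000655, or 0.267 with an estimated correlation). Of 20 matrix genes, 0 were higher and 10 lower (1 and 10 adjusted over the list alone, camera adjusted p = 2.68e-05, or 0.324 with an estimated correlation). COL6A2 (-2.25 ± 0.35, adjusted p = 0.000187) and COL3A1 (-2.15 ± 0.19, adjusted p = 7.74e-08), both collagen genes, were among them. Of 9 smooth muscle and pericyte genes, 0 were higher and 5 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.00459, or 0.318 with an estimated correlation). NOTCH3 (-3.17 ± 0.30, adjusted p = 2.1e-07) and the actin regulator gene LMOD1 (-1.89 ± 0.38, adjusted p = 0.0024) were among them. Of 12 sex steroid genes, 1 was higher and 7 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.00218, or 0.267 with an estimated correlation). AKR1C3 (-1.03 ± 0.15, adjusted p = 8.71e-05) was among them.

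Camera placed the lists that follow above the other genes in visceral adipocytes. Of 7 thermogenic genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00306, or 0.0708 with an estimated correlation). These were EBF2 (2.01 ± 0.21, adjusted p = 7.53e-07) and the lipid droplet gene CIDEA (1.34 ± 0.24, adjusted p = 0.000611). Of 28 oxidative phosphorylation genes, 4 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 2.68e-05, or 0.318 with an estimated correlation). COX5B, of cytochrome c oxidase, differed by 0.55 ± 0.15, adjusted p = 0.025, a call lost without the 2 shallowest visceral libraries (adjusted p = 0.0754), and SDHC, of succinate dehydrogenase, by 0.39 ± 0.10, adjusted p = 0.0139, a call lost with the donor as a block (adjusted p = 0.0729). Of 20 immediate early and heat shock genes, 5 were higher and 0 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.002, or 0.475 with an estimated correlation). HSPA1A (1.11 ± 0.26, adjusted p = 0.00706) and its near-identical copy HSPA1B (1.06 ± 0.22, adjusted p = 0.0028) were among them. Of 16 macrophage genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.00459, or 0.598 with an estimated correlation). Of 15 inflammatory genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.00306, or 0.534 with an estimated correlation). Values not called were 1.78 ± 0.73, adjusted p = 0.139 for the complement gene C1QA (positive in 8 of 9 donors) and 0.33 ± 0.18, adjusted p = 0.279 for the signaling suppressor gene SOCS3 (6 of 9). Without the 2 shallowest visceral libraries the lists of HOX, macrophage, inflammatory and immediate early genes did not pass (adjusted p = 0.0942, 0.154, 0.0942 and 0.0511), and those of mature adipocytes, lipolysis and preadipocytes did (0.00541, 0.0361 and 0.0278).

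A further 12 lists with at least 2 genes tested did not pass, with camera adjusted p between 0.0605 and 0.541. These were the lists of mesothelial cells, mature adipocytes, lipogenesis, lipolysis, adipokines, preadipocytes, blood endothelium, red blood cells, complement, glucocorticoid response, Wnt genes and cell cycle. Of 20 mature adipocyte genes, 5 were higher and 2 lower (6 and 2 adjusted over the list alone), and of 17 lipolysis genes 5 were higher and 4 lower (6 and 4). The medians of Wnt, complement and preadipocyte genes were -0.08, -0.00 and 0.07, while camera gave the opposite signs. No gene of the T and NK, B and plasma and mast cell lists was tested, and 1 lymphatic gene was. CALB2, a calcium-binding gene (-0.85 ± 0.13, adjusted p = 0.000168), and ELOVL6, a fatty acid elongase gene (-1.55 ± 0.35, adjusted p = 0.00585), were lower. The lipase inhibitor gene ANGPTL4 (-0.90 ± 0.19, adjusted p = 0.00341) and the cyclin gene CCNA2 (-0.75 ± 0.16, adjusted p = 0.00368) were lower too. ADRB1, an adrenergic receptor gene (1.21 ± 0.21, adjusted p = 0.000503), the angiotensinogen gene AGT (1.33 ± 0.24, adjusted p = 0.00094) and the Wnt amplifier gene RSPO3 (1.92 ± 0.13, adjusted p = 8.77e-10) were higher. Values not called were 0.76 ± 0.53, adjusted p = 0.396 for CLDN5 (positive in 5 of 9 donors), 1.08 ± 0.74, adjusted p = 0.396 for HBB (6 of 9) and 1.43 ± 0.55, adjusted p = 0.11 for LYVE1 (7 of 9), the last called with the donor as a random effect (adjusted p = 0.0446).

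In adipocytes 1335 of 14156 genes were called, 393 higher and 942 lower, and 327 by at least 1 log2 unit. With the donor as a random effect 2185 were called, and as a fixed block 1247, among them 76.0% of the 1335. The share that was higher was 29.4% over all runs, and the runs differed: in the latest run 45 of 271 calls were higher, and in earlier runs 1073 of 1752. Named genes not called in the latest run were LINC02458, HAS1, C7, CALB2, CIDEA, ELOVL6, AGT, COL6A2, HSPA1A, HSPA1B, COX5B, SDHC and CCNA2 (adjusted p 0.0516 to 0.233). HAS1, LMOD1, HSPA1A, COX5B, SDHC and ANGPTL4 were not called in earlier runs (0.0620 to 0.170). Without the filter HAS1, C7 and COX5B were not called (0.0551 to 0.0733), and COX5B and SDHC were not without the run covariate (0.239 and 0.449) or in donors with both depots (0.119 and 0.110).

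**Figure D3:**
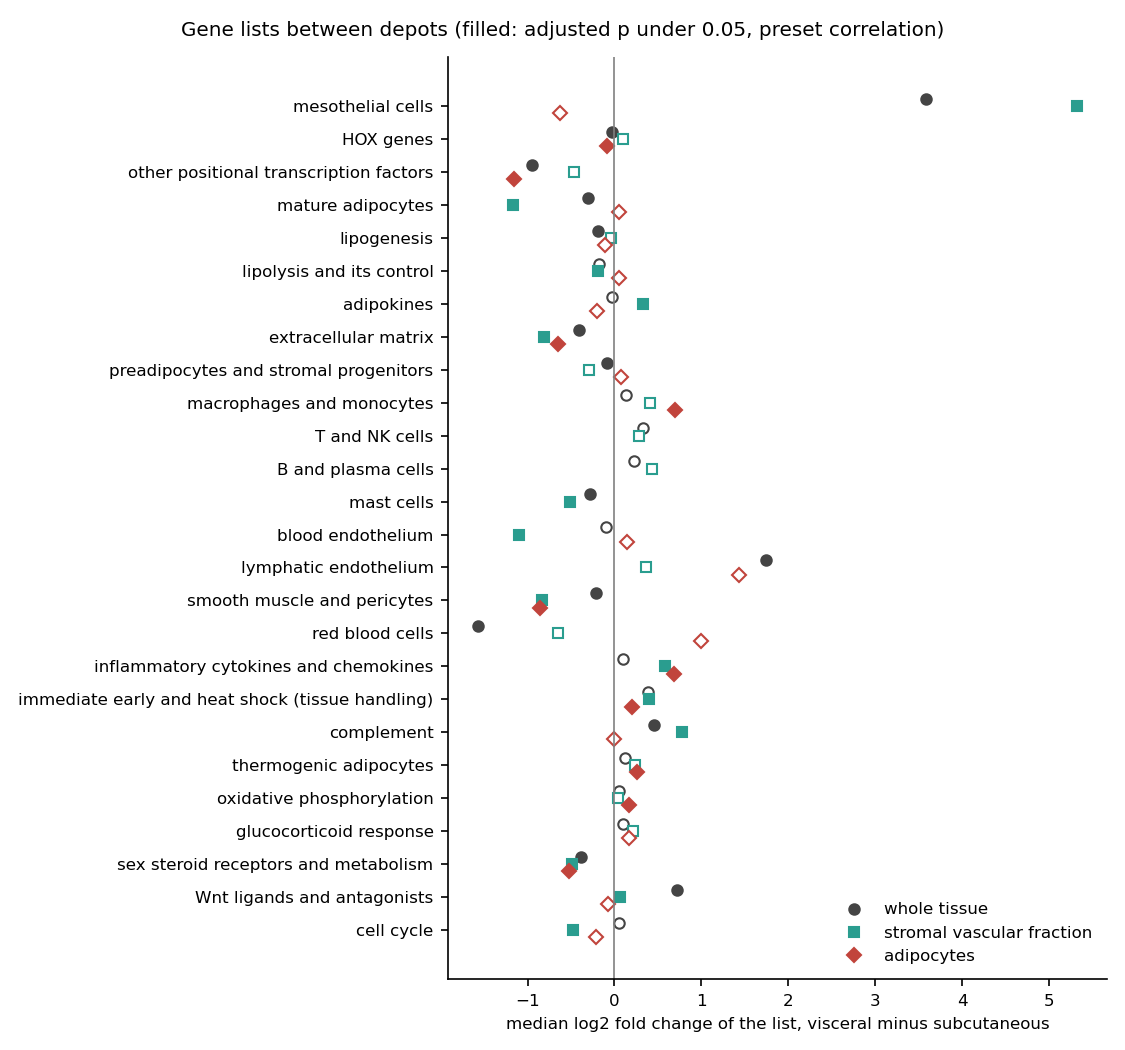
Median log2 difference, visceral minus subcutaneous, of the genes of each list in whole tissue (circles), stromal vascular fraction (squares) and adipocytes (diamonds). Filled symbols had a camera adjusted p under 0.05 with the preset correlation.

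Adipocytes were compared within each depot with the stromal vascular fraction, which was cryopreserved, so cell type and freezing are confounded. In subcutaneous fat LEP (ENSG00000174697, chromosome 7, 128241284 to 128257628), which encodes the satiety hormone leptin, rose from 8.6 ± 7.47 RPKM in 11 stromal vascular samples to 846 ± 335 in 12 adipocyte samples (SD), a difference of 6.45 ± 0.44, adjusted p = 3.16e-16. PLIN1 rose from 22.1 ± 16.6 to 1529.7 ± 327 RPKM, a difference of 6.35 ± 0.35, adjusted p = 4.62e-19. HBB (ENSG00000244734, chromosome 11, 5225464 to 5229395) fell from 41708 ± 93133 to 13.2 ± 16.1 RPKM (-11.06 ± 0.76, adjusted p = 3.96e-16). The library richest in hemoglobin raised the first mean, and without it the difference was -10.46 (adjusted p = 6.56e-16). Genes named for subcutaneous fat had the same sign in all 10 donors with both fractions, and those named for visceral fat in all 8. The visceral values of PLIN1 and HBB were 7.58 ± 0.36, adjusted p = 3.08e-21, and -9.23 ± 0.78, adjusted p = 1.25e-13.

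The acute phase gene SAA1 (ENSG00000173432, chromosome 11, 18266174 to 18269977), whose reads can be shared with SAA2, was higher in adipocytes of both depots (6.47 ± 0.61, adjusted p = 2.86e-12 and 7.88 ± 0.63, adjusted p = 2.22e-14). RBP4, a retinol carrier, and CIDEC differed by 6.25 ± 0.39, adjusted p = 3.44e-17, and 5.95 ± 0.36, adjusted p = 9.78e-18 in subcutaneous fat. GPD1, a glycerol phosphate dehydrogenase gene, and CIDEC differed by 7.19 ± 0.33, adjusted p = 2.04e-21, and 7.52 ± 0.37, adjusted p = 1.28e-20 in visceral fat. ALAS2, of heme synthesis, was lower in adipocytes of both depots (-7.68 ± 0.46, adjusted p = 9.74e-18 and -7.05 ± 0.48, adjusted p = 2.09e-16), as was the water channel gene AQP9 in visceral fat (-6.21 ± 0.47, adjusted p = 6.35e-15).

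In subcutaneous fat, of 20 mature adipocyte genes, 20 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 8.18e-20, or 0.0309 with an estimated correlation). Of the same genes in visceral fat, 20 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 1.15e-26, or 0.0163 with an estimated correlation). Of 18 lipogenesis genes 15 were higher and 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 3.41e-12, or 0.0309 with an estimated correlation) in subcutaneous fat. In visceral fat 15 were higher and 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 9.77e-12, or 0.0287 with an estimated correlation). THRSP (5.68 ± 0.43, adjusted p = 6.74e-15 and 6.92 ± 0.44, adjusted p = 4.04e-17) and the desaturase gene SCD (4.84 ± 0.51, adjusted p = 6.42e-11 and 5.91 ± 0.53, adjusted p = 5.9e-13) were among them. Of 17 lipolysis genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 1.3e-10, or 0.0293 with an estimated correlation) in subcutaneous fat. Among visceral samples 13 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 1.06e-12, or 0.01 with an estimated correlation). LIPE differed by 4.56 ± 0.28, adjusted p = 1.39e-17, and 5.78 ± 0.29, adjusted p = 1.78e-20. Of 28 oxidative phosphorylation genes 27 were higher and 0 lower (27 and 0 adjusted over the list alone, camera adjusted p = 2.7e-19, or 0.0309 with an estimated correlation) in subcutaneous fat. In visceral fat 27 were higher and 0 lower (27 and 0 adjusted over the list alone, camera adjusted p = 4.13e-22, or 0.0163 with an estimated correlation). COX7B (2.25 ± 0.18, adjusted p = 5.08e-14 and 2.26 ± 0.19, adjusted p = 8.13e-14), of the respiratory chain, was an example. Of 8 thermogenic genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.0291, or 0.212 with an estimated correlation) in subcutaneous fat. Among visceral samples 5 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.00244, or 0.0425 with an estimated correlation). The subcutaneous list did not pass after median-of-ratios rescaling (adjusted p = 0.0663). CIDEA (5.09 ± 0.30, adjusted p = 6.49e-18 and 6.40 ± 0.31, adjusted p = 1.06e-20) and COX7A1 (visceral, 5.05 ± 0.28, adjusted p = 6e-19) were higher, and the glycerol kinase gene GK lower (subcutaneous, -3.78 ± 0.34, adjusted p = 6.01e-13). Of 13 sex steroid genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 1.76e-06, or 0.0549 with an estimated correlation) in subcutaneous fat. In visceral fat 9 were higher and 2 lower (9 and 2 adjusted over the list alone, camera adjusted p = 3.21e-06, or 0.0533 with an estimated correlation). AKR1C2 (4.09 ± 0.22, adjusted p = 5.36e-19 and 5.17 ± 0.23, adjusted p = 5.76e-22) was among them. Of 23 HOX genes 10 were higher and 2 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00154, or 0.432 with an estimated correlation) in subcutaneous fat. Among visceral samples 7 were higher and 4 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.00378, or 0.534 with an estimated correlation).

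Most immune and stromal genes were lower in adipocytes. Of 14 T and NK cell genes 0 were higher and 14 lower (0 and 14 adjusted over the list alone, camera adjusted p = 1.37e-06, or 0.28 with an estimated correlation) in subcutaneous fat. In visceral fat 0 were higher and 14 lower (0 and 14 adjusted over the list alone, camera adjusted p = 3.98e-06, or 0.327 with an estimated correlation). Of 18 macrophage genes 0 were higher and 18 lower (0 and 18 adjusted over the list alone, camera adjusted p = 0.000108, or 0.436 with an estimated correlation) in subcutaneous fat. Among visceral samples 0 were higher and 18 lower (0 and 18 adjusted over the list alone, camera adjusted p = 0.00185, or 0.534 with an estimated correlation). Of 8 mast cell genes 0 were higher and 8 lower (0 and 8 adjusted over the list alone, camera adjusted p = 9.99e-05, or 0.218 with an estimated correlation) in subcutaneous fat. In visceral fat 0 were higher and 8 lower (0 and 8 adjusted over the list alone, camera adjusted p = 0.00143, or 0.327 with an estimated correlation). Of 8 red blood cell genes 0 were higher and 8 lower (0 and 8 adjusted over the list alone, camera adjusted p = 0.000118, or 0.28 with an estimated correlation) in subcutaneous fat. Among visceral samples 0 were higher and 8 lower (0 and 8 adjusted over the list alone, camera adjusted p = 0.00186, or 0.438 with an estimated correlation). Of 20 inflammatory genes 0 were higher and 17 lower (0 and 18 adjusted over the list alone, camera adjusted p = 0.00154, or 0.494 with an estimated correlation) in subcutaneous fat. In visceral fat 0 were higher and 19 lower (0 and 19 adjusted over the list alone, camera adjusted p = 0.00317, or 0.534 with an estimated correlation). Of 15 preadipocyte genes 2 were higher and 12 lower (2 and 12 adjusted over the list alone, camera adjusted p = 0.0176, or 0.518 with an estimated correlation) in subcutaneous fat. Among visceral samples 0 were higher and 13 lower (0 and 13 adjusted over the list alone, camera adjusted p = 0.019, or 0.534 with an estimated correlation). Of 14 cell cycle genes 0 were higher and 13 lower (0 and 13 adjusted over the list alone, camera adjusted p = 0.00258, or 0.432 with an estimated correlation) in subcutaneous fat. In visceral fat 0 were higher and 13 lower (0 and 13 adjusted over the list alone, camera adjusted p = 0.0384, or 0.56 with an estimated correlation).

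Of 20 mesothelial genes in visceral fat, 1 was higher and 19 lower (1 and 19 adjusted over the list alone, camera adjusted p = 1.17e-06, or 0.327 with an estimated correlation). ITLN1 (-6.16 ± 0.71, adjusted p = 4.45e-10) and KRT18 (-6.13 ± 0.53, adjusted p = 2.06e-13) were among them. In subcutaneous fat this list did not pass (camera adjusted p = 0.0692), and CALB2 was higher (5.74 ± 0.27, adjusted p = 3.02e-21). Of 17 adipokine genes 6 were higher and 7 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.0201, or 0.287 with an estimated correlation) in subcutaneous fat, with a median of -0.29 against a camera direction above the other genes. Lists that passed in neither depot had camera adjusted p between 0.0546 and 0.646 in subcutaneous and between 0.086 and 0.958 in visceral fat, where the adipokine list did not pass either (p = 0.0617). These were other positional factors, extracellular matrix, B and plasma cells, blood and lymphatic endothelium, smooth muscle, immediate early genes, complement, glucocorticoid response and Wnt genes. In subcutaneous fat the medians of mesothelial, smooth muscle, glucocorticoid and Wnt genes were -0.02, -0.19, -0.56 and -0.03, and in visceral fat those of other positional factors, adipokines, smooth muscle and glucocorticoid genes -0.18, -0.78, -1.08 and -0.83, while camera placed these lists above the other genes. Median-of-ratios rescaling made the blood and lymphatic endothelial lists pass in subcutaneous fat (adjusted p = 0.0377 and 0.0472) and the complement list in visceral fat (0.0439). Without the library richest in hemoglobin the mesothelial, blood endothelial and immediate early lists passed in subcutaneous (0.0376, 0.0254 and 0.0254) and adipokines in visceral fat (0.0405). Examples lower in subcutaneous adipocytes were the homeobox gene PRRX1 (-3.65 ± 0.37, adjusted p = 2.4e-11) and the collagen gene COL6A3 (-4.64 ± 0.34, adjusted p = 1.84e-15). HSD11B1, which activates cortisol, was higher (3.60 ± 0.24, adjusted p = 1.59e-16). In visceral adipocytes the fibronectin gene FN1 (-5.39 ± 0.45, adjusted p = 9.63e-14) and the complement gene C3 (-5.51 ± 0.43, adjusted p = 1.04e-14) were lower. The homeobox gene IRX6 (5.28 ± 0.20, adjusted p = 2.32e-24) and the adhesion gene MCAM (3.76 ± 0.31, adjusted p = 4.37e-14) were higher.

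Of 20901 genes tested, 15436 were called in subcutaneous fat, 4132 higher and 11304 lower in adipocytes, and 15870 in visceral fat, 3637 higher and 12233 lower. The median difference of all genes was -0.55 and -0.69, and -0.37 and -0.46 after median-of-ratios rescaling, so values are relative to these shifts. The share of calls that were higher in visceral fat was 22.9% as deposited and 33.1% after that rescaling. Only the latest run held both fractions, so both comparisons rest on it.

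The depot difference itself differed between fractions, tested as adipocytes minus stromal vascular fraction. Positive values mean a higher visceral minus subcutaneous difference in adipocytes. For EGFL6 subcutaneous and visceral means were 3.65 ± 3 and 3.51 ± 1.86 RPKM in the stromal vascular fraction and 182 ± 82.9 and 3.42 ± 4.4 in adipocytes (SD, n = 11, 11, 12 and 10), a difference of differences of -6.20 ± 0.61, adjusted p = 2.42e-10. For KRT8 the means were 0.239 ± 0.168 and 86 ± 39.2, against 1.31 ± 0.414 and 4.72 ± 8.51 (-6.17 ± 0.49, adjusted p = 8.26e-13). CCDC3 (ENSG00000151468, chromosome 10, 12896625 to 13099652), which encodes a secreted protein of fat and vessels, had means of 6.45 ± 3 and 4.26 ± 3.07, against 65.2 ± 14.2 and 295 ± 53.6 (2.77 ± 0.36, adjusted p = 1.79e-07). FABP4 had means of 1225 ± 637 and 288 ± 141, against 3918 ± 1508 and 5447 ± 1701 (2.54 ± 0.35, adjusted p = 4.82e-07).

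Positive differences were also found for LINC02458 (2.55 ± 0.39, adjusted p = 5.93e-06), the connexin gene GJC1 (2.53 ± 0.34, adjusted p = 3.12e-07) and GDF10 (2.43 ± 0.32, adjusted p = 2e-07). Negative ones were found for the transglutaminase gene TGM1 (-6.05 ± 0.49, adjusted p = 1.59e-12), the haptoglobin gene HP (-5.80 ± 0.48, adjusted p = 2.56e-12) and KRT18 (-5.59 ± 0.63, adjusted p = 5.5e-09). Of 20 mesothelial genes, 0 were higher and 19 lower (0 and 20 adjusted over the list alone, camera adjusted p = 7.55e-54, or 0.00042 with an estimated correlation). Of 20 mature adipocyte genes, 13 were higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 1.59e-15, or 0.107 with an estimated correlation). The glycerol channel gene AQP7 (1.79 ± 0.29, adjusted p = 1.8e-05) was among them. Of 17 lipolysis genes, 7 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.000771, or 0.346 with an estimated correlation), with AQP3 at -1.53 ± 0.32, adjusted p = 0.000602. Of 12 blood endothelial genes, 2 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 2.78e-05, or 0.598 with an estimated correlation). These were the endothelial genes ESAM (1.77 ± 0.58, adjusted p = 0.0411) and EMCN (1.65 ± 0.54, adjusted p = 0.0418). Of 15 complement genes, 0 were higher and 6 lower (0 and 7 adjusted over the list alone, camera adjusted p = 0.000157, or 0.38 with an estimated correlation). CFB (-3.21 ± 0.38, adjusted p = 2.35e-08) and C4A (-2.91 ± 0.36, adjusted p = 4.43e-08) were among them. Of 8 thermogenic genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00558, or 0.107 with an estimated correlation). EBF2 (1.81 ± 0.33, adjusted p = 8.16e-05) and COX7A1 (1.57 ± 0.33, adjusted p = 0.000761) were among them. Of 28 oxidative phosphorylation genes, 3 were higher and 0 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.00864, or 0.736 with an estimated correlation). COX5B (0.54 ± 0.18, adjusted p = 0.0412) and COX5A (0.54 ± 0.14, adjusted p = 0.00915) were among them. Of 8 mast cell genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0152, or 0.65 with an estimated correlation). No mast cell gene passed the filter in adipocytes alone, so this list rests mainly on the stromal vascular fraction. Of 8 red blood cell genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0107, or 0.65 with an estimated correlation). Of 14 cell cycle genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.00977, or 0.65 with an estimated correlation). Values not called were 0.58 ± 0.48, adjusted p = 0.51 for the mast cell gene CPA3, 1.83 ± 0.93, adjusted p = 0.227 for HBB and 0.02 ± 0.25, adjusted p = 0.973 for PCNA. Without the library richest in hemoglobin the red blood cell and cell cycle lists did not pass (adjusted p = 0.129 and 0.0582), and without the 2 shallowest visceral adipocyte libraries the mast cell list did not (0.0559).

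The other 16 lists did not pass, with camera adjusted p between 0.0866 and 0.994. The Wnt list passed with the donor as a block (adjusted p = 0.0486) and without the 2 shallowest libraries (0.00774), and other positional factors after median-of-ratios rescaling (0.0482). The medians of lipogenesis, matrix, B and plasma cell, lymphatic, immediate early, glucocorticoid and sex steroid genes were -0.14, -0.08, -0.24, -0.24, -0.22, -0.07 and -0.14, while camera placed these lists above the other genes. Of their members HOXC8 (-2.00 ± 0.17, adjusted p = 1.03e-11), WT1 (-4.41 ± 0.33, adjusted p = 1.81e-13), ELOVL6 (-1.62 ± 0.38, adjusted p = 0.00263) and ITLN1 (-4.34 ± 0.84, adjusted p = 0.000243) were negative. MFAP5 (-2.37 ± 0.57, adjusted p = 0.00343), PDPN (-2.23 ± 0.36, adjusted p = 1.11e-05), DES (-2.38 ± 0.42, adjusted p = 6.33e-05) and CXCL6 (-2.42 ± 0.30, adjusted p = 4.29e-08) were negative too. H6PD (-1.06 ± 0.22, adjusted p = 0.00069) and RSPO1 (-5.55 ± 0.43, adjusted p = 3.75e-13) were also negative, and the elastin gene ELN positive (1.69 ± 0.34, adjusted p = 0.000415). Values not called were 0.94 ± 0.79, adjusted p = 0.518 for C1QA, -0.55 ± 0.54, adjusted p = 0.592 for CCL5, -0.62 ± 0.74, adjusted p = 0.668 for JCHAIN and -0.72 ± 0.25, adjusted p = 0.0562 for DUSP1, the last called with the donor as a fixed block or random effect and without the 2 shallowest libraries (adjusted p = 0.0162, 0.0285 and 0.0305).

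In all 2261 of 20901 genes were called, 576 positive and 1685 negative. The share that was positive was 25.5% as deposited, 37.8% after median-of-ratios rescaling and 36.2% without the library richest in hemoglobin. In the latest run alone 680 genes were called, 34 positive, and LINC02458, ELOVL6, ITLN1, ELN, ESAM, EMCN, DES, EBF2, COX7A1, COX5B, COX5A and H6PD were not (adjusted p 0.0523 to 0.608). With limma voom ITLN1 and PDPN were smaller (-2.32 and -0.57) and not called, and ESAM, EMCN, DES and CXCL6 were not called at 2.01, 2.05, -2.02 and -1.85 (adjusted p of the 6 genes 0.184 to 0.801). ESAM, EMCN and COX5B were not called without the 2 shallowest libraries (0.109 to 0.121) or without the filter (0.0624 to 0.0731), nor with COX5A without the run covariate (0.0927 to 0.229). With a pseudocount of 0.1 ESAM and EMCN were not (0.0754 and 0.134), and COX5B was not without the library with most genes detected (0.0546).

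The depot differences of whole tissue were shared with each cell fraction. Of the genes tested in both, 955 were higher in visceral whole tissue and stromal vascular fraction, against 199.6 for independent calls (odds ratio 17.2), and 279 were lower in both, against 47.0 (odds ratio 11.4). Whole tissue and adipocytes shared 185 higher genes against 42.6 (odds ratio 8.36) and 387 lower ones against 51.2 (24.0). The 2 cell fractions, which share donors, shared 95 higher genes against 30.0 (4.25) and 150 lower ones against 50.5 (3.96). Adjusted over 18 tests these 6 had p of at most 4.62e-25. Genes higher in the stromal vascular fraction and lower in adipocytes numbered 81, against 72.0 (adjusted p = 0.266), and 15 with differences of at least 1 log2 unit, against 4.26 (odds ratio 3.89, adjusted p = 2.94e-05). Across genes, which are not independent, the Pearson correlation of the differences was 0.74 between whole tissue and stromal vascular fraction, 0.55 between whole tissue and adipocytes and 0.20 between the fractions. Of 12952 genes tested in all 3 comparisons, 195 were called in each with the same sign, 79 higher and 116 lower in visceral fat.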

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

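The tests in this part were planned, but how many genes are named, and so tested, was chosen after the values were seen. A sample stood apart from the rest of its group in 17 of 188 pairs of a named gene and a group, by the gap to its nearest neighbour as a share of the group's range, and chance gives about 1 in 20. In visceral whole tissue the share was high for a low value of ITLN1 (0.488) and RSPO1 (0.561), and for a high value of TBX15 (0.606). In subcutaneous whole tissue low values were those of HOXC8 (0.4934), PNPLA3 (0.498) and EBF2 (0.475), and high values those of WT1 (0.476), HSPA1B (0.558) and WNT5A (0.65). In visceral adipocytes a high value stood apart for NRCAM (0.751), HOXC9 (0.712), CCL5 (0.554), IL7R (0.627), WT1 (0.555), DES (0.706) and CXCL6 (0.549), and a low one for SCD (0.558).

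The depot difference, visceral minus subcutaneous, differed between adipocytes and stromal vascular fraction for 53 of 92 named genes, by the interaction term of the joint limma fit (adjusted p 5.13e-14 to 0.0418). Some were named because they were called by this term, so the share is no estimate for other genes, and of all genes 2261 of 20901 (10.8%) were called. Values are log2 differences, adipocytes minus stromal vascular fraction. Positive values were found for CCDC3 (2.77), LINC02458 (2.55), FABP4 (2.54), GJC1 (2.53), GDF10 (2.43), XG (2.15) and BARX1 (2.13). Smaller positive values were found for CTHRC1 (1.86), EBF2 (1.81), AQP7 (1.79), ESAM (1.77), ELN (1.69), EMCN (1.65) and CIDEC (1.57). The smallest positive values were those of COX7A1 (1.57), CIDEA (1.31), ADRB1 (1.25), LIPE (1.21), AKR1C2 (1.08), COX5B (0.54) and COX5A (0.54). Negative values reached their largest size for EGFL6 (-6.20), KRT8 (-6.17), TGM1 (-6.05), HP (-5.80), KRT18 (-5.59), RSPO1 (-5.55), MSLN (-5.11) and CLDN1 (-5.08). Further negative values were found for CALB2 (-4.57), NRCAM (-4.44), WT1 (-4.41), ITLN1 (-4.34), CFB (-3.21), C4A (-2.91), C4B (-2.81) and CXCL6 (-2.42). Next in size were DES (-2.38), MFAP5 (-2.37), PDPN (-2.23), WNT5A (-2.10), HOXC8 (-2.00), GREM1 (-1.86), ELOVL6 (-1.62) and COL6A2 (-1.56). Smaller negative values were those of NOTCH3 (-1.54), AQP3 (-1.53), LIF (-1.25), NR2F1 (-1.19), TBX15 (-1.18), H6PD (-1.06) and HOXC9 (-0.90). Reads of C4A and C4B, and of the AKR1C genes, can be shared.

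By camera 10 lists also differed between fractions (adjusted p 7.55e-54 to 0.0152). Their median differences were -4.46 for mesothelial cells, 1.24 for mature adipocytes, 0.38 for lipolysis, 0.47 for mast cells and 1.33 for blood endothelium. They were 0.73 for red blood cells, -0.77 for complement, 0.21 for thermogenic adipocytes, 0.10 for oxidative phosphorylation and 0.29 for cell cycle. With an estimated correlation only the mesothelial list of these 10 passed (adjusted p = 0.000420).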

How the results depend on the processing

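Some alternatives, named above, were chosen after seeing the data. Requiring 1 log2 unit left 534 calls in whole tissue, 1080 in the stromal vascular fraction, 327 in adipocytes, 8800 and 9581 between fractions in subcutaneous and visceral fat, and 1211 for the difference between fractions. It left 272 higher and 72 lower genes shared by whole tissue and stromal vascular fraction, 33 and 70 by whole tissue and adipocytes, and 20 and 42 by the fractions. With the replicate block whole tissue had 4994 calls (5399 as a random effect), adipocytes 2185 as a random effect, and 447 lower genes were shared by whole tissue and stromal vascular fraction. The latest run alone, with fewer samples, gave 838 calls in the stromal vascular fraction, 271 in adipocytes and 680 for the difference between fractions. Without the run covariate there were 581 calls in adipocytes and 1504 for the difference between fractions. Adipocytes of donors with both depots gave 596 calls, with fewer samples, and voom gave 2412. The difference of GREM1 between fractions was -1.86 (adjusted p = 0.00167) and 0.97 with voom (adjusted p = 0.721), and the cause was not tested. Of the alternatives for 434 named gene results, 6054 kept call and sign, 218 lost the call, 5 gained it and 1 turned sign. For lists 661 kept it, 82 lost it, 65 of these with an estimated correlation, and 21 gained it. The first library of each donor alone was not run, since the deposited columns combine them.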

Other observations

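Of 12 blood endothelial genes 12 were lower in subcutaneous and 6 in visceral adipocytes than in the stromal vascular fraction, and of 7 lymphatic genes 7 in each, though neither list passed against the other genes. In subcutaneous fat the endothelial adhesion gene PECAM1 differed by -3.37 ± 0.49, adjusted p = 8.46e-08, and LYVE1 by -3.80 ± 0.52, adjusted p = 2.67e-08. In visceral fat KDR differed by -3.03 ± 0.49, adjusted p = 7.39e-07, and PDPN by -4.15 ± 0.30, adjusted p = 1.48e-15. The plasma cell gene JCHAIN was lower in adipocytes of both depots (-2.93 ± 0.60, adjusted p = 3.94e-05 and -3.56 ± 0.62, adjusted p = 2.67e-06).

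Below, the run tests of whole-tissue calls of at least 1 log2 unit and of mesothelial genes were chosen only after the result was seen. So were the alternatives without single libraries. Of 100 random splits per comparison that part as many donor pairs, only the real one called as many genes. The others held the real difference as residual, which lowers calls, so chance stays open. Real and highest other counts were 3209 and 1 in whole tissue, 2969 and 2250 in the stromal vascular fraction, and 1335 and 515 in adipocytes. They were 15436 and 13690 between fractions in subcutaneous fat, 15870 and 13072 in visceral fat, and 2261 and 749 for the difference between fractions. The highest other split moved 2 libraries in the stromal vascular fraction, in adipocytes and between subcutaneous fractions, and so was close to the real one. It moved 16 of 21 between visceral fractions, 5 short of the mirror image, 4 in whole tissue and 14 for the difference between fractions. The median of other splits was 0 in each.

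Depot calls in whole tissue are confounded with the sequencing run. Of calls of at least 1 log2 unit tested in the stromal vascular fraction, where each run holds both depots, 97.3% had the same sign there, against 63.6% for independent signs, and of smaller calls 87.4% against 58.6%, which argues against the run as the whole cause. After correction for GC content and gene length 98.7% of the larger calls were kept with the same sign, which argues against such a bias for them. Of the smaller calls 65.0% were kept (75.2% with the replicate block), and the median size went from 0.40 to 0.36. The correction also recentred the libraries, as did median-of-ratios rescaling, which kept 74.8% of all calls, so for the smaller calls that were lost bias, scale and depot cannot be told apart. In adipocytes 81.5% of the smaller calls had the same sign, against 50.5% for independent signs, which a bias or scale of the whole-tissue table alone would not give. Run effects on single genes, and a biological difference between depots, stay open.

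Mesothelial genes were higher in the visceral stromal vascular fraction. Across its libraries the genes moved together within runs (mean pairwise Spearman correlation 0.713, against at most 0.272 in 1000 random lists), as varying numbers of mesothelial cells would give. The run was argued against by median differences of 5.80 and 5.04 in the runs taken alone. Mesothelial cells in the visceral samples are a candidate explanation, and the most abundant of these genes, ITLN1, reached 1042 ± 573 RPKM (SD, n = 11). Whether such cells belong to the depot or came with the dissection stays open and was not tested.

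Of 20 mature adipocyte genes 11 were higher in subcutaneous than visceral stromal vascular fraction. The library richest in hemoglobin lowers subcutaneous values, so the 15 calls made without it do not test the cause. RNA of mature adipocytes in the subcutaneous samples is a candidate explanation, which would raise all markers by the same share of their adipocyte level. The excess was within a factor 2 of the median share of 1.56% for 10 of 20 markers, and reached 23.9% for FABP4, 22.8% for PPARG and 35.4% for CD36, genes that other stromal cells also express. As a share of their depot's adipocyte level, all 20 markers but DGAT2 were higher in subcutaneous samples. PLIN1 was at 1.44% against 0.519%, DGAT2 at 3.55% against 5.14%. Carried-over RNA and a difference between stromal cells could both give this and cannot be told apart.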
